A study of Arabidopsis thaliana with 24 samples.

How the data were processed

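RNA was measured in whole Arabidopsis thaliana seedlings by Illumina sequencing of total RNA extracted with TRIzol, per the labels. The 24 libraries were 2 for each combination of 3 genotypes (WT, pif7-1 and ref6-1), 2 histories (naive or primed) and 2 lights (white light or 1 h of shade). The deposited values were TPM, made by the authors for all genes of 1 table. The submitters' processing notes name FastQC, cutadapt, STAR, HTSeq and DESeq2 and the genome build TAIR10, without versions or roles. How TPM was computed, the gene lengths used and the strandedness of the libraries were not given in the sources used here. TPM keeps no read counts, so the depth of each library and the counting precision of each value are unknown. The table held 33026 genes, of which 193 were assembled loci without a gene identifier (183 of them tested), and no column lacked a sample. Groups came from the sample titles, and each replicate number was used as given.

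Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3. Genes with at least 1 TPM in at least 2 libraries were kept, 21473 in all. A linear model with 12 group means was fitted to all 24 libraries, which left 12 residual degrees of freedom, and variances were moderated with a trend on mean expression (prior degrees of freedom 3.69). The 24 comparisons were shade against white light in each genotype and history, primed against naive, mutant against WT, and the differences between these differences. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. In 26 gene lists with 376 genes, written from general knowledge before the data were examined, 344 members were tested, with camera (preset correlation of 0.01, and with an estimated correlation) and with fry. Adjustment over the list alone means that the adjusted p was computed within the members of 1 list. Of the tested list members 87 overlapped another annotated gene, and a call for such a gene may count reads of its neighbour.

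Genes named in the text followed a rule fixed before the data were examined, as were the comparisons, the model and most alternatives. For each comparison these were the 10 largest and 10 smallest log2 fold changes among the genes that passed, and for 2 groups also with all libraries separated. The text could stop after 5 each way in comparisons with a mutant. From each list up to 4 passing members with the largest change were named, or the 2 with the smallest p where none passed, and PIF7 and REF6 always. A named gene kept its values in other comparisons. Gene names and overlaps came from a reference annotation of build TAIR10.1, which differs from the build of the authors, so no positions are printed.

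The procedure was tested on simulated data with 50 changed genes for each fold, so error in the real data is unknown. For WT naive shade it called 18 of 50 genes changed by 1.5-fold, 38 by 2-fold, 48 by 4-fold and 45 by 8-fold, and 6 of 21273 unchanged genes. For the WT interaction it called 6, 20, 48 and 40 of 50. Alternatives were a minimum of 5 TPM, no filter beyond a TPM above 0, pseudocounts of 0.1 and 5, quantile normalization, the replicate number as a block, only the libraries of the compared groups, and the omission of each library. Added after the data were examined were nuclear genes only, mitochondrial TPM as a covariate, genes that overlap no other gene, a fit without the 8 naive mutant libraries, and all alternatives for the overlap between the mutants. Overlap between the mutants was judged against 40 simulations in which both mutants equalled WT. Naive mutant against naive WT levels, and primed against naive mutant levels in white light alone, were not tested. The naive mutant libraries form a later deposit block. Primed against naive levels of the mutants in shade, and averaged over lights against WT, were analysed and share that limit, as do single gene levels printed for naive mutants.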

Results

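Gene expression was measured by RNA sequencing in whole Arabidopsis thaliana seedlings of the Col-0 wild type (WT) and of lines labelled pif7-1 and ref6-1. PIF7 encodes a bHLH transcription factor that drives much of the response to shade, and REF6 encodes a Jumonji-type demethylase that removes a repressive histone mark. Seedlings aged 4 days spent 8 h either in white light (naive) or in shade (primed), recovered in white light for 40 h, and then stayed in white light or received 1 h of triggering shade at a red to far-red ratio of about 0.5. Each of the 12 combinations of genotype, history and light had 2 libraries, 24 in all. Values were TPM, which summed to the same total in each library within rounding. Between 18614 and 20007 genes reached 1 TPM in a library. Across genes, log2 values of replicates correlated with r from 0.961 to 0.985, against 0.904 to 0.977 between libraries of different groups. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Adjusted p-values for genes are from limma, and those for gene lists are from camera with a preset correlation of 0.01. A lone number in parentheses after a gene name is its log2 fold change or, for a test of a difference in response, the difference of log2 fold changes. Chance alone separates all libraries of 2 groups of 2 in 33.3% of genes.

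The targeted genes were examined first. PIF7 (AT5G61270) stood at 65.7 ± 15.4 TPM in naive white light, 43.4 ± 1.51 TPM in naive shade, 62.5 ± 6.82 TPM in primed white light and 28.9 ± 0.799 TPM in primed shade in WT (mean ± SD, n = 2). In pif7-1 the corresponding values were 2.87 ± 0.226, 1.72 ± 0.424, 2.27 ± 0.354 and 1.82 ± 1.03 TPM, and no pif7-1 library exceeded 3.03 TPM. In ref6-1 they were 42.4 ± 4.46, 31.3 ± 5.85, 54.6 ± 7.92 and 20.2 ± 1.51 TPM. PIF7 overlaps another annotated gene, and strandedness was not stated. REF6 (AT3G48430) levels overlapped between the genotypes. It stood at 11.3 ± 2.27, 9.41 ± 0.636, 8.7 ± 0.813 and 11 ± 0.438 TPM in WT in the same order, at 10.4 ± 0.771, 10 ± 0.0212, 11.7 ± 0.969 and 8.62 ± 3.2 TPM in pif7-1, and at 9.78 ± 1.65, 8.3 ± 0.969, 6.5 ± 0.481 and 8 ± 0.276 TPM in ref6-1. Gene totals cannot show where a transcript is interrupted, so REF6 does not check the label of the ref6-1 libraries. Below, ref6-1 stands for the libraries labelled ref6-1. Other genes set the naive and primed ref6-1 libraries apart. ATXR7 (AT5G42400), a histone H3 lysine methyltransferase gene, stayed at or below 0.02 TPM in all 4 naive ref6-1 libraries, against 7.2 to 8.6 TPM in the primed ones, 6.83 to 12.9 TPM in WT and 4.44 to 9.94 TPM in pif7-1.

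**Figure D1:**
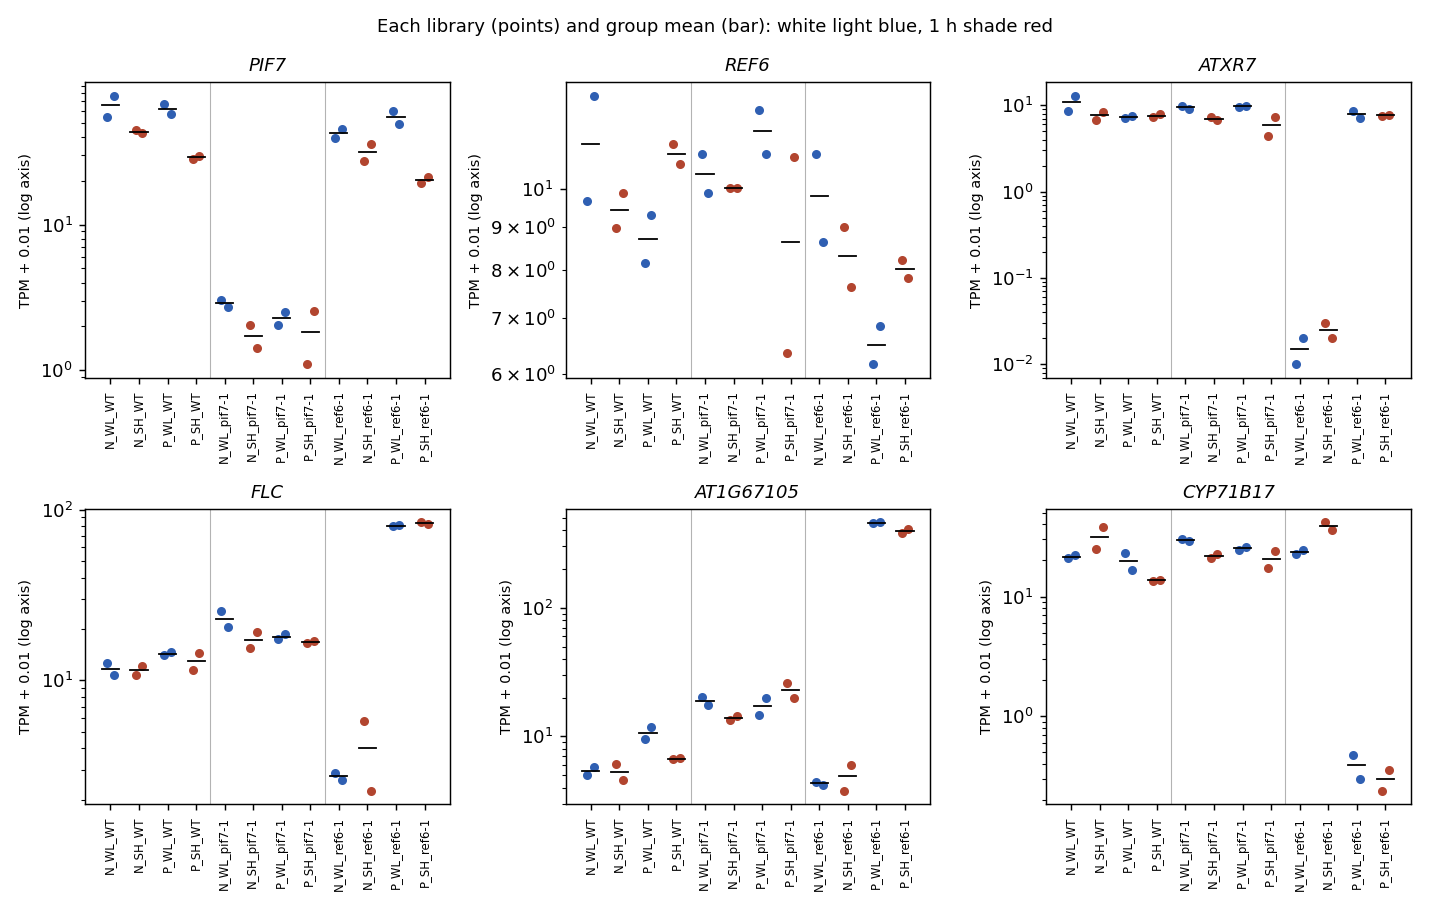
TPM of PIF7, REF6, ATXR7, FLC, AT1G67105 and CYP71B17 in the 24 libraries, on a log axis of TPM + 0.01. Points are libraries, bars are group means of 2, blue is white light and red is 1 h of shade; PIF7 stays at or below 3.03 TPM in pif7-1, and ATXR7 stays at or below 0.02 TPM in the naive ref6-1 libraries but not in the primed ones.

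The first comparison asked how naive WT seedlings responded to 1 h of shade. PIL1 (AT2G46970), a bHLH gene among the fastest to respond to a low red to far-red ratio, went from 1.25 ± 0.177 to 64.5 ± 4.73 TPM (mean ± SD, n = 2; log2 fold change 4.86, SE 0.16, adjusted p = 1.57e-11). The homeodomain gene ATHB2 (AT4G16780) went from 13.4 ± 3.3 to 281 ± 2.04 TPM (log2 fold change 4.31, SE 0.17, adjusted p = 2.86e-10). All 15 tested members of this list rose, among them HFR1 (3.4) and PAR1 (2.67), which encode atypical bHLH proteins that restrain elongation (camera adjusted p = 6.93e-18). YUC8 (AT4G28720), which encodes a flavin monooxygenase of auxin synthesis, rose from 4.66 ± 0.0212 to 42.5 ± 9.86 TPM (log2 fold change 2.92, SE 0.22, adjusted p = 2.54e-07), while the aminotransferase gene TAA1 fell by 1.87 on the log2 scale. In the auxin synthesis list 3 of 9 genes rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.339). Of 19 Aux/IAA and GH3 genes, early targets of auxin, 12 rose and 1 fell (camera adjusted p = 8.07e-11, or 0.0674 with an estimated correlation), and the largest rises were IAA29 (4.13), IAA6 (3.54) and IAA19 (3.29). All 17 SAUR genes, small auxin-induced genes that promote cell expansion, rose (camera adjusted p = 1.65e-22). SAUR22 (3.89), SAUR68 (3.17) and SAUR23 (3.11) led them, but SAUR19 to SAUR24 are near-identical copies whose reads cannot be divided with certainty. For the early shade, Aux/IAA and SAUR lists the counts adjusted over the list alone were the same. Ethylene synthesis genes rose in 5 of 7 cases and fell in 1 (the same adjusted over the list alone), led by the ACC synthase genes ACS8 (3.1) and ACS4 (2.51) (camera adjusted p = 0.00159, or 0.283 with an estimated correlation).

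Growth hormone and cell wall genes moved both ways. Among 20 expansin and XTH genes, whose products loosen cell walls, 5 rose and 5 fell (5 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.411), with XTH22 at 2.54 and XTH31 at -1.61. Of 17 gibberellin genes 7 rose and 1 fell (7 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0503), including the synthesis genes GA20OX1 (1.72) and GA20OX2 (1.36). The median of that list was -0.04 although its mean and test pointed upward. Brassinosteroid genes gave 5 rises and 4 falls of 13 (5 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.351), with the inactivating enzyme gene BAS1 (AT2G26710) at 1.13 and the synthesis gene BR6OX1 at -1.54. Cytokinin response genes gave 2 rises and 5 falls of 12 (2 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.424), with ARR3 at -1.55. Clock genes rose in 8 of 23 cases and fell in 3 (9 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.00695, or 0.57 with an estimated correlation), led by the pseudo-response regulator gene PRR7 (2.32) and by RVE7 (2.28). Among light signalling genes 4 of 18 rose and 1 fell (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.339), with PIF4 at 1.12 and the photoreceptor gene PHYB at 1.01. The median of the light signalling list was -0.01, opposite in sign to its mean and test. B-box genes rose in 4 of 12 cases (4 higher and 0 lower adjusted over the list alone), led by BBX29 (2.41) (camera adjusted p = 0.0351, or 0.57 with an estimated correlation). Light-harvesting genes rose in 7 of 18 and fell in 1 (7 higher and 1 lower adjusted over the list alone), with LHCB1.4 at 1.52 and LHCB4.3 at -1.44 (camera adjusted p = 0.00544, or 0.608 with an estimated correlation). The list calls of the B-box and light-harvesting genes were lost under quantile normalization.

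In naive WT shade, of 17 genes of the flavonoid list, which also holds the light-stress genes ELIP1 and ELIP2, 8 fell and none rose (0 higher and 11 lower adjusted over the list alone), including the entry enzyme gene CHS (-1.83) and FLS1 (-1.94) (camera adjusted p = 0.00729, or 0.57 with an estimated correlation). Carbon starvation genes rose in 3 of 4 cases (the same adjusted over the list alone), with SEN1 (AT4G35770) at 3.23 and the asparagine synthetase gene ASN1 at 3.12 (camera adjusted p = 0.00452, or 0.305 with an estimated correlation). Touch and wound genes rose in 5 of 17 (4 higher and 0 lower adjusted over the list alone), among them CBF2 (1.29) (camera adjusted p = 0.0248, or 0.57 with an estimated correlation). Flowering regulators rose in 4 of 12 and fell in 1 (6 higher and 1 lower adjusted over the list alone), with SVP at 0.98 (camera adjusted p = 0.0337, or 0.449 with an estimated correlation). Chromatin regulators gave 1 rise and 4 falls of 23 (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.726), with the remodelling ATPase gene SYD at -0.89. Its test pointed upward against a median of -0.01 and a mean of -0.09. Drought genes gave 2 rises of 12 (2 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.387), COR15B at 1.4 among them. Their list had a median of -0.01 against a mean of 0.1. Salicylate genes gave 2 falls of 7 (the same adjusted over the list alone; camera adjusted p = 0.874), including the pathogenesis-related gene PR5 (-1.3). The direction of that list turned under quantile normalization. Jasmonate genes gave 1 fall of 4 (the same adjusted over the list alone; camera adjusted p = 0.411), VSP1 at -1.03. Boundary genes gave 1 fall of 9, CUC3 at -0.69 (0 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.991), with a median of -0.11 against an upward test. No gene passed among 9 heat shock genes (camera adjusted p = 0.0963) or 9 mitosis markers (camera adjusted p = 0.784), with 0 in both lists also adjusted over the list alone. The mitosis markers had a median of -0.1 and a mean of 0 beside an upward test. Root markers fell in 10 of 13 cases and rose in 1 (1 higher and 10 lower adjusted over the list alone), with the root hair wall gene PRP3 at -2.66 (camera adjusted p = 0.0197, or 0.57 with an estimated correlation). Just 1 seed storage marker of 8 rose, EM6 at 0.91 (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.203). Mitochondrial transcripts took 321 to 559 TPM in the naive shaded WT libraries and 158 to 407 TPM in those of ref6-1, against 59 to 186 TPM in all others.

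Across the genome 7650 of 21473 tested genes passed in naive WT, 2681 higher and 4969 lower in shade, with 2223 changed by more than 2-fold. Among the 20 genes with the largest changes, 14 were not protein coding and 15 overlapped another gene, so their values are uncertain. The small nucleolar RNA gene SNOR108 (AT5G41471) was listed at 365 and 894 TPM in naive shaded WT and at 0 in the other 22 libraries. CYS1 (AT5G12140), a cysteine protease inhibitor gene, was listed at 0 in both naive shaded WT libraries and at 107 and 70 TPM in naive white light. Other large rises were the mitochondrial ribosomal RNA RRN5 (7.61) and AT3G08785 (7.25), and other large falls were MIR2936 (-6.16) and AT5G23411 (-5.95). The median of all genes was -0.0986, and quantile normalization, which moved it to 0.004, gave 4170 higher and 4369 lower genes. Without replicate 2 of the white-light group it was 3082 higher and 3057 lower. The count was 3450 with only the compared groups in the fit, 3458 with mitochondrial TPM as a covariate, and 4763 without replicate 1 of the naive shaded group.

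**Figure D2:**
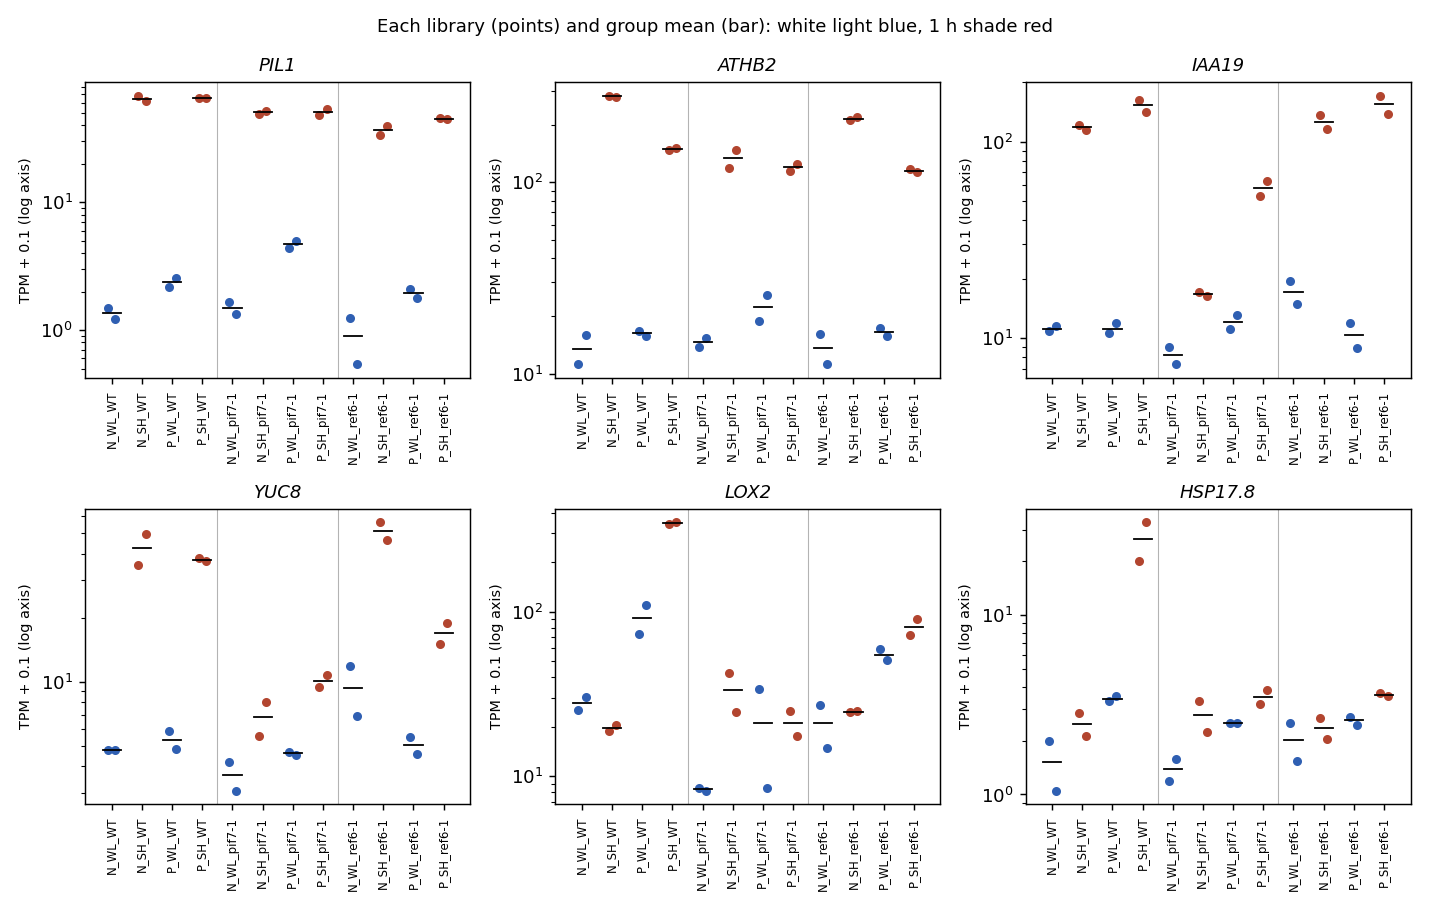
TPM of PIL1, ATHB2, IAA19, YUC8, LOX2 and HSP17.8 in the 24 libraries, on a log axis of TPM + 0.1. Points are libraries, bars are group means of 2, blue is white light and red is 1 h of shade; in shaded WT the mean of PIL1 is 64.5 TPM in naive and 64.8 TPM in primed seedlings, and that of LOX2 is 348 TPM in primed ones.

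Whether primed seedlings answered the same hour of shade was examined next in WT. PIL1 rose from 2.26 ± 0.283 to 64.8 ± 0.198 TPM (mean ± SD, n = 2; log2 fold change 4.34, SE 0.16, adjusted p = 1.82e-10) and ATHB2 from 16.2 ± 0.728 to 150 ± 2.4 TPM (log2 fold change 3.13, SE 0.17, adjusted p = 2.18e-08). Of the 15 early shade genes 11 rose and none fell, the same adjusted over the list alone (camera adjusted p = 3.57e-11, or 0.0548 with an estimated correlation). YUC9 (2.75) and YUC8 (2.63) rose and TAA1 fell by 1.25 on the log2 scale, among 4 rises and 2 falls in 9 auxin synthesis genes, the same adjusted over the list alone (camera adjusted p = 0.148). Aux/IAA and GH3 genes rose in 16 of 19 cases (17 higher and 0 lower adjusted over the list alone; camera adjusted p = 7.03e-13, or 0.0548 with an estimated correlation), led by IAA6 (3.91). All 17 SAUR genes rose, the same adjusted over the list alone, led by SAUR22 (2.78) (camera adjusted p = 8.81e-16, or 0.0709 with an estimated correlation). Heat shock genes rose in 7 of 9 cases, the same adjusted over the list alone (camera adjusted p = 1.25e-06, or 0.0724 with an estimated correlation). The small heat shock gene HSP17.8 stood at 3.32 ± 0.148 before and 26.5 ± 9.18 TPM after shade (log2 fold change 2.63), and the chaperone gene HSP90.1 rose by 2.55. The small heat shock genes are close copies of each other. Jasmonate genes rose in 3 of 4 cases, the same adjusted over the list alone (camera adjusted p = 0.00715, or 0.314 with an estimated correlation). The lipoxygenase gene LOX2 (AT3G45140) went from 91.7 ± 26.4 to 348 ± 4.87 TPM (log2 fold change 1.94, SE 0.43, adjusted p = 0.00456).

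In primed WT shade, expansin and XTH genes rose in 6 of 20 cases and fell in 1 (9 higher and 1 lower adjusted over the list alone), with XTH17 at 2.61 (camera adjusted p = 0.00685, or 0.488 with an estimated correlation). Gibberellin genes rose in 7 of 17 and fell in 1 (9 higher and 2 lower adjusted over the list alone), led by GA20OX1 (2.25) (camera adjusted p = 0.0249, or 0.488 with an estimated correlation). Ethylene synthesis genes rose in 6 of 7, the same adjusted over the list alone, led by ACS8 (2.76) (camera adjusted p = 7.73e-05, or 0.108 with an estimated correlation). Carbon starvation genes rose in 3 of 4, likewise unchanged over the list alone, with ASN1 at 2.34 (camera adjusted p = 0.0132, or 0.314 with an estimated correlation). Of the flavonoid list 3 of 17 genes fell, the same adjusted over the list alone, ELIP1 (-2.05), ELIP2 (-1.4) and the flavonoid gene F3H (-0.68) (camera adjusted p = 0.015, or 0.613 with an estimated correlation). Flowering regulators fell in 2 of 12 (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0259, or 0.314 with an estimated correlation), MAF2 at -0.71 and MAF3 at -0.59. Touch and wound genes fell in 6 of 17 and rose in 2 (3 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.07), with ZAT10 at -1.72. Root markers rose in 4 of 13 and fell in 1 (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.105). In all 5035 genes passed, 3115 higher and 1920 lower (3338 higher and 2879 lower under quantile normalization), 1125 of them by more than 2-fold. Beyond PIL1, the sulfotransferase gene SOT15 (4.1) was among the 10 largest rises, and the indole metabolism gene CYP71A12 (-4.51) and the glutathione transferase genes GSTF7 (-4.15) and GSTF6 (-4.01) were among the 10 largest falls. LHCB1.5, a light-harvesting gene that overlaps AT2G08665, was listed at 0 in both primed white-light WT libraries and at 16800 and 14900 TPM in primed shade. Leaving out any 1 of the 4 libraries gave 2219 to 3355 genes, fewest without replicate 2 of the shaded group.

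The lasting effect of the priming treatment was read in white light, 40 h after it ended. Compared with naive WT, touch and wound genes were higher in 7 of 17 cases (10 higher and 0 lower adjusted over the list alone), with the zinc finger gene ZAT10 (log2 fold change 1.83, SE 0.28, adjusted p = 0.00152) and WRKY33 (1.4) (camera adjusted p = 1.91e-12, or 0.0524 with an estimated correlation). Heat shock genes were higher in 5 of 9 (6 higher and 0 lower adjusted over the list alone; camera adjusted p = 5.72e-09, or 0.0524 with an estimated correlation). Jasmonate genes were higher in 3 of 4, the same adjusted over the list alone, with VSP2 at 2.01 and LOX2 at 1.67 (camera adjusted p = 8.06e-06, or 0.085 with an estimated correlation). B-box genes were higher in 7 of 12 (7 higher and 1 lower adjusted over the list alone), led by BBX30 (1.61) (camera adjusted p = 4.3e-08, or 0.085 with an estimated correlation). Light-harvesting genes were higher in 8 of 18 with 1 lower (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.91e-12, or 0.187 with an estimated correlation). Their mean was -0.06 against a median of 0.58, since LHCB1.5 was listed at 0 in primed white light. SAUR genes were higher in 4 of 17, the same adjusted over the list alone (camera adjusted p = 4.95e-07, or 0.297 with an estimated correlation). Expansin and XTH genes were lower in 6 of 20 (0 higher and 8 lower adjusted over the list alone), with XTH4 at -1.23 (camera adjusted p = 0.0241, or 0.528 with an estimated correlation). Root markers were lower in 2 of 13 (0 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.00644, or 0.527 with an estimated correlation). Clock genes went both ways, 5 higher and 7 lower of 23 (6 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.625), with the evening genes TOC1 at -1.46 and ELF3 at -1.34. The list median was 0.07 and the mean -0.11, and its direction turned under quantile normalization. The histone demethylase gene JMJ30, which follows the clock, was lower (-2.53). Among the 10 largest rises were CYP71A12 (5.2), FOX1 (3.94), GSTF6 (3.88) and GSTF7 (3.75), of indole defence compound and detoxification pathways. In all 1616 genes passed, 398 higher and 1218 lower (921 and 888 under quantile normalization, with the median of all genes going from -0.144 to -0.001). With only these 4 libraries in the fit limma called 0 genes (3567 at an unadjusted p under 0.05). The count was 476 without replicate 2 of the naive group and 756 and 480 without replicates 1 and 2 of the primed group.

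The levels reached in shade were then compared between primed and naive WT. Jasmonate and heat shock genes ended higher in primed seedlings. LOX2 stood at 348 ± 4.87 TPM against 19.4 ± 1.22 TPM (mean ± SD, n = 2; log2 fold change 4.09, SE 0.43, adjusted p = 5.65e-06). All 4 jasmonate genes were higher, the same adjusted over the list alone (camera adjusted p = 0.000326, or 0.269 with an estimated correlation). Heat shock genes were higher in 8 of 9, the same adjusted over the list alone, led by HSP90.1 (3.28) (camera adjusted p = 3.57e-06, or 0.269 with an estimated correlation). Flavonoid list genes were higher in 9 of 17, the same adjusted over the list alone, with DFR at 1.8 and CHS at 1.48 (camera adjusted p = 0.029, or 0.873 with an estimated correlation). Lower in primed shade were 10 of 15 early shade genes (0 higher and 11 lower adjusted over the list alone), among them FHL (-1.5) and ATHB4 (-1.36) (camera adjusted p = 0.00993, or 0.745 with an estimated correlation). SAUR genes were lower in 7 of 17, the same adjusted over the list alone (camera adjusted p = 0.0177, or 0.873 with an estimated correlation). Clock genes were lower in 13 of 23 and higher in 2 (3 higher and 13 lower adjusted over the list alone), with FKF1 at -1.76 (camera adjusted p = 0.00368, or 0.764 with an estimated correlation). Flowering regulators were lower in 7 of 12 (1 higher and 7 lower adjusted over the list alone), led by MAF2 (-1.76) (camera adjusted p = 0.00993, or 0.394 with an estimated correlation). Root markers were higher in 9 of 13 and lower in 1 (9 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0585), in the comparison against the naive shaded libraries with high mitochondrial TPM. In all 9257 genes passed, 4747 higher and 4510 lower (5265 higher and 4873 lower under quantile normalization, 3083 higher and 3662 lower without replicate 1 of the naive group), and 2594 with mitochondrial TPM as a covariate. Of the 20 genes with the largest differences 19 were not protein coding or overlapped another gene.

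A test of the difference between the primed and the naive shade response in WT showed which genes responded differently after priming. The jasmonate genes VSP2 (log2 fold change 2.5, SE 0.82, adjusted p = 0.0271) and LOX2 (log2 fold change 2.42, SE 0.61, adjusted p = 0.00627) responded more strongly in primed seedlings. So did all 4 members of their list (4 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0179, or 0.537 with an estimated correlation). Heat shock genes gave a more positive response in 6 of 9 (7 higher and 0 lower adjusted over the list alone), with HSP90.1 at 2.35 (camera adjusted p = 0.012, or 0.537 with an estimated correlation). SAUR genes gave a less positive response in 9 of 17 (0 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.000138, or 0.537 with an estimated correlation). Early shade genes did so in 4 of 15, the same adjusted over the list alone, including ATHB2 (-1.18) (camera adjusted p = 0.00612, or 0.537 with an estimated correlation). PIL1 did not pass, at a difference of -0.52 (SE 0.22). B-box genes had negative differences in 6 of 12 and positive in 1, the same adjusted over the list alone (camera adjusted p = 0.00612, or 0.537 with an estimated correlation). Clock genes had 9 negative and 2 positive of 23 (2 higher and 10 lower adjusted over the list alone), with PRR7 at -2.03 (camera adjusted p = 0.013, or 0.697 with an estimated correlation). Flowering regulators had 7 negative of 12, the same adjusted over the list alone, with MAF2 at -1.66 (camera adjusted p = 0.00612, or 0.537 with an estimated correlation). Touch genes had 6 negative and 1 positive of 17 (1 higher and 7 lower adjusted over the list alone), with ZAT10 at -1.86 (camera adjusted p = 0.00612, or 0.537 with an estimated correlation). Root markers had positive differences in 10 of 13 and 1 negative, the same adjusted over the list alone, with PRP3 at 4.31 (camera adjusted p = 0.0119, or 0.61 with an estimated correlation). In all 7594 genes passed, 4939 with a more positive and 2655 with a more negative response in primed seedlings. Quantile normalization gave 4410 higher and 4094 lower, with the median of all genes going from 0.123 to -0.007. With mitochondrial TPM as a covariate the count was 2944.

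The size of the WT response was compared over the 4896 genes that passed for the mean of the naive and primed responses, 1978 higher and 2918 lower, but 2827 higher and 2989 lower under quantile normalization and 2274 higher and 1998 lower without replicate 2 of naive white light. PIL1 (4.6), IAA29 (3.88) and ATHB2 (3.72) led the early shade and auxin genes of this set. All 15 early shade genes and all 17 SAUR genes rose in it, the same adjusted over the list alone (camera adjusted p = 6.63e-23 for the early shade genes). Genes of the higher set had median changes of 0.53 in naive and 0.5 in primed seedlings, and camera gave p = 0.00752 for the difference, or p = 0.455 with an estimated correlation. Genes of the lower set had median changes of -0.79 in naive and -0.39 in primed seedlings, with p = 0.0014, or p = 0.488 with an estimated correlation. The slope of primed on naive changes was 0.59 across these genes, and 0.26 with mitochondrial TPM as a covariate. Of the genes called in both responses, 464 rose in both (389 by chance from the sizes of the lists), 459 fell in both (444 by chance) and 1459 moved in opposite directions (961 by chance).

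**Figure D3:**
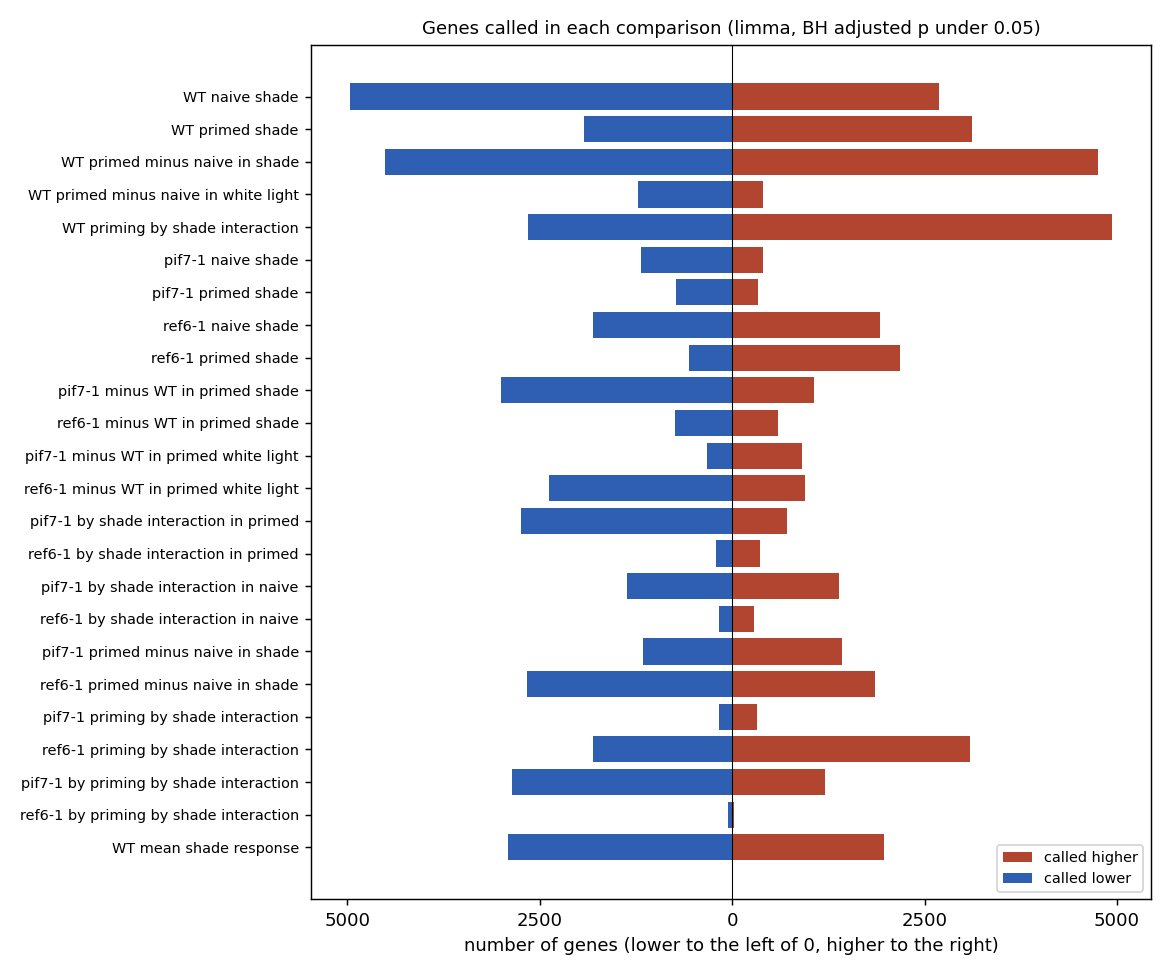
Numbers of genes past an adjusted p of 0.05 in the 24 comparisons, as horizontal bars from 0, with lower genes to the left in blue and higher genes to the right in red. WT primed minus naive in shade has the most, 4747 higher and 4510 lower.

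The need for PIF7 in the first shade response was tested in naive pif7-1. PIL1 went from 1.4 ± 0.233 to 50.3 ± 1.59 TPM (mean ± SD, n = 2; log2 fold change 4.42, SE 0.16, adjusted p = 1.36e-10), and 6 of 15 early shade genes rose (10 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.11e-13). IAA19 went from 8.13 ± 1.2 to 16.7 ± 0.396 TPM in pif7-1 and from 11.1 ± 0.382 to 118 ± 5.2 TPM in WT, and its response differed from WT by -2.33 on the log2 scale (SE 0.23, adjusted p = 2.08e-05). The responses of YUC8 (-2.16) and YUC9 (-2.02) also differed from WT. Less positive responses than in WT were found in 10 of 19 Aux/IAA and GH3 genes (0 higher and 14 lower adjusted over the list alone; camera adjusted p = 8.14e-12, or 0.0521 with an estimated correlation). The same held for 16 of 17 SAUR genes (0 higher and 17 lower adjusted over the list alone), with SAUR68 at -2.29 (camera adjusted p = 2.74e-15, or 0.0583 with an estimated correlation), and for 9 of 15 early shade genes (0 higher and 11 lower adjusted over the list alone), with PAR1 at -2.63 (camera adjusted p = 4.1e-09, or 0.0521 with an estimated correlation). All 4 carbon starvation genes responded more negatively, the same adjusted over the list alone (camera adjusted p = 7.27e-07, or 0.0521 with an estimated correlation). SEN1 (AT4G35770) fell by 1.74 on the log2 scale in pif7-1, whereas it rose in WT. Clock genes responded less positively in 9 of 23 and more in 1, the same adjusted over the list alone, with PRR7 at -3.06 (camera adjusted p = 5.22e-06, or 0.31 with an estimated correlation). Flavonoid list genes responded more positively in 6 of 17 (8 higher and 0 lower adjusted over the list alone), with FLS1 at 2.29 (camera adjusted p = 3.01e-06, or 0.312 with an estimated correlation). Ethylene synthesis genes responded less positively in 4 of 7, the same adjusted over the list alone, led by ACS4 (-1.97) (camera adjusted p = 0.00644, or 0.312 with an estimated correlation). In all 1584 genes passed for shade in naive pif7-1, 406 higher and 1178 lower (951 higher and 982 lower under quantile normalization). The difference from WT passed in 2764, 1394 higher and 1370 lower (1944 higher and 1750 lower under quantile normalization), and the direction with more genes turned in 8 other fits. The first count was 4 with only the compared groups in the fit and 377 to 844 without any 1 of its libraries. The second was 1465 with the compared groups, 1118 with mitochondrial TPM as a covariate, and 1129 without replicate 1 of shaded pif7-1. It was 1600 to 1823 without either white-light pif7-1 library, either shaded WT library or replicate 1 of white-light WT.

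The same test in primed pif7-1 asked whether the response after priming needed PIF7. PIL1 rose from 4.57 ± 0.424 to 50.4 ± 3.56 TPM (mean ± SD, n = 2; log2 fold change 3.21, SE 0.16, adjusted p = 1.84e-08). Early shade genes rose in 8 of 15 cases (13 higher and 0 lower adjusted over the list alone; camera adjusted p = 8.73e-23). SAUR genes rose in 15 of 17 (17 higher and 0 lower adjusted over the list alone), led by SAUR19 (2.07) (camera adjusted p = 3.26e-35). No SAUR gene differed from WT in its primed response, nor adjusted over the list alone (camera adjusted p = 0.73). The auxin synthesis genes YUC9 (-3.16), YUC2 (-1.65) and YUC8 (-1.64) responded less than in WT. So did 11 of 19 Aux/IAA and GH3 genes (0 higher and 13 lower adjusted over the list alone), led by IAA5 (-1.98) (camera adjusted p = 0.000164, or 0.733 with an estimated correlation). Heat shock genes responded less in 4 of 9 (0 higher and 6 lower adjusted over the list alone), led by HSP17.8 (-2.26) (camera adjusted p = 0.012, or 0.733 with an estimated correlation). Among early shade genes 5 responded less (camera adjusted p = 0.17), the same adjusted over the list alone, with CKX5 at -1.97. Touch genes responded more positively in 5 of 17 (6 higher and 0 lower adjusted over the list alone), led by ZAT10 (2.09) (camera adjusted p = 0.00021, or 0.733 with an estimated correlation). The defence and detoxification genes CYP71A12 (6.76), GSTF7 (6.64) and FOX1 (5.96), all high in primed white-light WT, were among the 10 largest positive differences. For shade in primed pif7-1 1075 genes passed, 341 higher and 734 lower, but 192 higher and 133 lower without replicate 1 of the shaded group. Quantile normalization gave 660 higher and 701 lower, with the median of all genes going from -0.121 to -0.008. For the difference from WT 3457 passed, 717 higher and 2740 lower, against 1642 higher and 2290 lower under quantile normalization, with the median of all genes going from -0.145 to -0.006. With only the compared groups in the fit limma called 0 genes for shade (2521 at an unadjusted p under 0.05) and 1282 for the difference. Without any 1 library the shade count ran from 178 to 3449, highest without replicate 2 of shaded pif7-1. For the difference it was 1409 to 2162 without either shaded WT library, either white-light pif7-1 library or replicate 1 of white-light WT, lowest without replicate 2 of shaded WT.

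Levels in primed pif7-1 were set directly against primed WT. In shade the jasmonate genes stood lower in all 4 cases, the same adjusted over the list alone (camera adjusted p = 2.45e-05, or 0.141 with an estimated correlation). LOX2 stood at 21.1 ± 5.19 TPM against 348 ± 4.87 TPM (mean ± SD, n = 2; log2 fold change -4, SE 0.43, adjusted p = 2.22e-05). Heat shock genes were lower in 8 of 9, the same adjusted over the list alone, with HSP17.8 at -2.6 (camera adjusted p = 8.93e-07, or 0.141 with an estimated correlation). Aux/IAA and GH3 genes were lower in 11 of 19 (2 higher and 13 lower adjusted over the list alone), led by IAA5 (-2.97) (camera adjusted p = 3.11e-05, or 0.442 with an estimated correlation). Flavonoid list genes were lower in 8 of 17 (0 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.000515, or 0.611 with an estimated correlation). YUC9 (-3.51) and the cold-response gene COR15A (-2.31) also stood lower. Root markers were lower in 5 of 13 and higher in 1 (1 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.0181, or 0.611 with an estimated correlation). In primed white light PIF7 itself was among the 5 largest falls (log2 fold change -4.28, SE 0.22, adjusted p = 1.75e-08). Carbon starvation genes were higher in 3 of 4 (4 higher and 0 lower adjusted over the list alone), led by ASN1 (2.99) (camera adjusted p = 3.11e-06, or 0.185 with an estimated correlation). Touch genes were lower in 5 of 17 (0 higher and 6 lower adjusted over the list alone; camera adjusted p = 3.11e-06, or 0.269 with an estimated correlation). AT2G01422, a non-coding RNA gene, stood at 58.6 to 97.4 TPM in the pif7-1 libraries and at 0.65 TPM or less in all others. Shade gave 4063 genes, 1059 higher and 3004 lower (2107 higher and 2673 lower under quantile normalization). White light gave 1223, 902 higher and 321 lower (1085 higher and 778 lower). With only the compared groups in the fit limma called 1 and 3 genes (4817 and 5414 at an unadjusted p under 0.05). The shade count was 1884 and 1386 without replicates 1 and 2 of shaded WT. The white-light count was 679, 287 and 154 without replicates 1 and 2 of white-light WT and replicate 2 of white-light pif7-1.

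Shade responses of the ref6-1 libraries came next. In naive seedlings PIL1 rose from 0.795 ± 0.502 to 36.5 ± 4.28 TPM (mean ± SD, n = 2; log2 fold change 4.41, SE 0.16, adjusted p = 1.24e-10). Early shade genes rose in 14 of 15 cases (15 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.85e-19). All 17 SAUR genes rose, the same adjusted over the list alone, led by SAUR23 (3.14) (camera adjusted p = 1.34e-24). Aux/IAA and GH3 genes rose in 10 of 19 (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.16e-07, or 0.198 with an estimated correlation). Root markers fell in 10 of 13 and rose in 1 (1 higher and 11 lower adjusted over the list alone; camera adjusted p = 3.99e-06, or 0.249 with an estimated correlation), in the group with the second highest mitochondrial TPM. Mitosis markers fell in 5 of 9, the same adjusted over the list alone (camera adjusted p = 0.00198, or 0.394 with an estimated correlation). In primed seedlings PIL1 rose from 1.84 ± 0.212 to 44.6 ± 0.601 TPM (log2 fold change 4.01, SE 0.16, adjusted p = 3.07e-10). Rises were found in 12 of 15 early shade genes (13 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.22e-13) and in 14 of 17 SAUR genes (16 higher and 0 lower adjusted over the list alone; camera adjusted p = 3.2e-14, or 0.0972 with an estimated correlation). Aux/IAA and GH3 genes rose in 12 of 19 (18 higher and 0 lower adjusted over the list alone), IAA19 by 3.78 (camera adjusted p = 3.2e-14), and YUC9 rose by 3.15. Expansin and XTH genes rose in 12 of 20 (13 higher and 2 lower adjusted over the list alone), led by XTH17 (2.99) (camera adjusted p = 1.97e-06, or 0.136 with an estimated correlation). B-box genes fell in 8 of 12, the same adjusted over the list alone (camera adjusted p = 7.12e-06, or 0.136 with an estimated correlation). Clock genes fell in 11 of 23 and rose in 6 (7 higher and 12 lower adjusted over the list alone), with PRR9 at -1.41 (camera adjusted p = 0.00801, or 0.515 with an estimated correlation). That list call was lost under quantile normalization. Seed storage markers fell in 4 of 8, the same adjusted over the list alone (camera adjusted p = 6.68e-05, or 0.136 with an estimated correlation). The 4 were EM6, EM1, OLEO1 and OLEO2, while CRA1, at 8.84 and 85.7 TPM in the white-light libraries, did not pass. The storage protein gene SESA5, at 3.95 and 117 TPM there, rested on 1 library for its log2 difference of 4.59 from WT. In naive seedlings 3735 genes passed, 1925 higher and 1810 lower, but 2374 higher and 2739 lower under quantile normalization and 1206 higher and 2259 lower without replicate 1 of the shaded group. In primed ones 2735 passed, 2181 higher and 554 lower (1739 higher and 1317 lower under quantile normalization). The naive count was 42 with only the compared groups in the fit and 854 with mitochondrial TPM as a covariate (292 higher and 562 lower). It was 1209, 2063 and 1741 without replicates 1 and 2 in white light and replicate 2 in shade. The primed count was 1109 with the compared groups and 813 to 1535 without any 1 library.

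Tests of the difference in shade response between ref6-1 and WT gave fewer genes than those for pif7-1 in each history, without a test of that contrast. In naive seedlings no early shade, Aux/IAA and GH3 or SAUR gene differed, with 1, 0 and 0 lower adjusted over the list alone, although their medians were negative. The list tests gave camera adjusted p = 0.00188, or 0.374 with an estimated correlation for the early shade genes. The SAUR genes gave camera adjusted p = 5.26e-05, or 0.44 with an estimated correlation, and the auxin response genes camera adjusted p = 2.26e-06, or 0.271 with an estimated correlation. The carbon starvation genes ASN1 (-3.54) and SEN1 (AT4G35770) (-3.44) and the clock gene PRR7 (-1.85) responded less positively than in WT. For ASN1 this went with a high white-light level in naive ref6-1, 109 ± 32.8 TPM, and 80.1 ± 16.4 TPM in shade. Naive WT had 5.62 ± 0.566 and 57.1 ± 12 TPM, so the difference is not a lower level in shade. In primed seedlings heat shock genes responded less in 3 of 9 (0 higher and 5 lower adjusted over the list alone), with HSP17.8 at 3.5 ± 0.106 TPM in shaded ref6-1 and 26.5 ± 9.18 TPM in shaded WT (mean ± SD, n = 2). The difference in its response was -2.26 (camera adjusted p = 7.04e-08, or 0.131 with an estimated correlation for the list). Jasmonate genes responded less in 2 of 4 (0 higher and 3 lower adjusted over the list alone), VSP1 at -2.07 (camera adjusted p = 3.07e-05, or 0.138 with an estimated correlation). Carbon starvation genes responded less in 2 of 4 (0 higher and 3 lower adjusted over the list alone; camera adjusted p = 5.07e-05, or 0.138 with an estimated correlation). All 4 stood higher than WT in primed white light, as given below. Touch genes responded more positively in 4 of 17 (6 higher and 1 lower adjusted over the list alone), led by ZAT10 (2.43) (camera adjusted p = 5.31e-05, or 0.363 with an estimated correlation). PIF4 responded less (-1.54). The difference passed in 458 genes in naive seedlings, 281 higher and 177 lower (309 higher and 331 lower under quantile normalization, with the median of all genes going from 0.114 to -0.009). It passed in 568 in primed seedlings, 359 higher and 209 lower (473 higher and 368 lower under quantile normalization). With only the compared groups in the fit the counts were 66 and 869. Leaving out any 1 library other than replicate 1 of white-light WT gave 169 to 944 in naive seedlings, highest without replicate 2 of shaded ref6-1. In primed seedlings the same gave 133 to 299, lowest without replicate 2 of shaded WT.

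Levels in primed ref6-1 were set against primed WT. In shade, heat shock genes were lower in 8 of 9, the same adjusted over the list alone (camera adjusted p = 1.08e-12), led by HSP17.6II (log2 fold change -2.89, SE 0.22, adjusted p = 7.99e-07), a small heat shock gene. FLC (AT5G10140), a repressor of flowering that overlaps another gene, stood at 83.6 ± 1.15 TPM against 13 ± 2.11 TPM in WT (mean ± SD, n = 2; log2 fold change 2.6, SE 0.23, adjusted p = 3.89e-06), and the floral activator genes SOC1 (-1.26) and FT (-1.13) were lower. LOX2 (-2.09) and AOS (-0.89) of the jasmonate list were lower, 2 of 4 over all genes (0 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.000323, or 0.268 with an estimated correlation). Clock genes were higher in 8 of 23 and lower in 2 (9 higher and 5 lower adjusted over the list alone), with FKF1 at 1.78 (camera adjusted p = 0.00971, or 0.753 with an estimated correlation). JMJ30 stood higher (log2 fold change 2.21). In white light all 4 carbon starvation genes were higher, the same adjusted over the list alone, with SEN1 (AT4G35770) at 3.68 (camera adjusted p = 8.23e-08, or 0.0766 with an estimated correlation). Clock genes were higher in 8 of 23 (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.57e-06, or 0.31 with an estimated correlation). Mitosis markers were lower in 6 of 9 (0 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.000212, or 0.31 with an estimated correlation). Seed storage markers were higher in 3 of 8 (4 higher and 0 lower adjusted over the list alone, the last being CRC, at 2.59 and 45.5 TPM; camera adjusted p = 5.74e-06, or 0.279 with an estimated correlation). The detoxification and defence genes GSTF7 (-6.36), GSTF6 (-5.37), CYP71A12 (-5.32) and FOX1 (-4.03), high in primed white-light WT, were among the 10 largest falls. The non-coding RNA gene AT1G67105 was the largest rise in both lights (5.69 and 5.32). Shade gave 1336 genes, 596 higher and 740 lower, but 876 higher and 843 lower under quantile normalization. White light gave 3332, 952 higher and 2380 lower (1779 higher and 1953 lower under quantile normalization). With only the compared groups in the fit the counts were 2013 and 426. Without any 1 library the shade count was 522 to 552, and the white-light count was 1236 and 1360 without replicate 2 of WT and of ref6-1.

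Whether priming acted differently in the mutants was read in shade and as an interaction, though their naive and primed libraries form separate deposit blocks. In primed against naive shaded pif7-1, expansin and XTH genes were higher in 12 of 20 and lower in 1 (14 higher and 1 lower adjusted over the list alone), led by XTH17 (2.29) (camera adjusted p = 2.16e-08, or 0.331 with an estimated correlation). SAUR genes were higher in 10 of 17 (14 higher and 0 lower adjusted over the list alone; camera adjusted p = 2.16e-08, or 0.331 with an estimated correlation). Aux/IAA and GH3 genes were higher in 8 of 19 (10 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.21e-06, or 0.331 with an estimated correlation). IAA19 stood at 16.7 ± 0.396 in naive and 57.8 ± 7.06 TPM in primed shade (mean ± SD, n = 2; log2 fold change 1.73, SE 0.16, adjusted p = 2.78e-05). The primed shade response of pif7-1 exceeded its naive response for XTH33 (2.57), IAA6 (1.69) and IAA19 (1.22). In 7 of 20 expansin and XTH genes the difference was positive and in 1 negative (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.83e-06, or 0.393 with an estimated correlation). This change in response was more positive than in WT in 10 of 17 SAUR genes (14 higher and 0 lower adjusted over the list alone), led by SAUR68 (2.02) (camera adjusted p = 1.14e-08, or 0.444 with an estimated correlation). It was also more positive in 6 of 17 touch genes (8 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.000199, or 0.444 with an estimated correlation). Jasmonate genes had a more negative change in 3 of 4 (0 higher and 4 lower adjusted over the list alone), LOX2 at -4 (camera adjusted p = 0.00663, or 0.444 with an estimated correlation), and flavonoid list genes in 6 of 17 (0 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.00599, or 0.556 with an estimated correlation). Primed shaded pif7-1 differed from naive shaded pif7-1 in 2590 genes, 1428 higher and 1162 lower, but 1636 higher and 1791 lower under quantile normalization and 1902 higher and 2462 lower without replicate 2 of the primed group. Its 2 shade responses differed in 489, 317 higher and 172 lower, but 720 higher and 1113 lower without that library and 470 higher and 384 lower under quantile normalization. The difference from WT in that change passed in 4076 genes, 1210 higher and 2866 lower (2179 higher and 2788 lower under quantile normalization, with the median of all genes going from -0.165 to -0.013). With only the compared groups limma called 0 genes for the levels (3064 at an unadjusted p under 0.05) and 5 for the responses (3025), where quantile normalization gave 854. Leaving out any 1 library gave 939 to 4364 and 47 to 1833, both highest without replicate 2 of primed shaded pif7-1. The last count was 1186 with mitochondrial TPM as a covariate, and 2598 and 2521 without replicate 2 of naive white-light and replicate 1 of naive shaded pif7-1.

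Since ATXR7 sets the naive and primed ref6-1 libraries apart, comparisons between them do not separate priming from plant line or clock state. The shaded libraries differed between histories at FLC, which stood at 4 ± 2.47 TPM in naive and 83.6 ± 1.15 TPM in primed shade (mean ± SD, n = 2; log2 fold change 4.17, SE 0.23, adjusted p = 1.2e-08). SAUR genes were lower in primed shade in 10 of 17 (0 higher and 12 lower adjusted over the list alone), led by SAUR68 (-1.47) (camera adjusted p = 0.000104, or 0.751 with an estimated correlation). Early shade genes were lower in 8 of 15 (0 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.00214, or 0.751 with an estimated correlation). Flavonoid list genes were higher in 7 of 17 (9 higher and 0 lower adjusted over the list alone), led by LDOX (1.73) (camera adjusted p = 0.000482, or 0.751 with an estimated correlation). The primed response was less positive than the naive one in 7 of 17 SAUR genes (0 higher and 8 lower adjusted over the list alone; camera adjusted p = 2.24e-05, or 0.425 with an estimated correlation) and in ATHB2 (-1.17) and HFR1 (-1.02). It was more positive in 10 of 13 root markers, with 1 less (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.24e-05, or 0.425 with an estimated correlation) and in 6 of 9 mitosis markers (7 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.00191, or 0.425 with an estimated correlation). Few genes separated this change from that of WT. The chaperone gene HSP90.1 (-2.17) and the jasmonate genes VSP1 (-2.98) and AOS (-1.58) passed. That was 1 of 9 heat shock genes (0 higher and 7 lower adjusted over the list alone; camera adjusted p = 1.43e-06, or 0.105 with an estimated correlation) and 2 of 4 jasmonate genes (0 higher and 3 lower adjusted over the list alone; camera adjusted p = 2.63e-05, or 0.105 with an estimated correlation). The level comparison passed in 4514 genes, 1854 higher and 2660 lower (2984 higher and 2628 lower under quantile normalization, 1998 higher and 1432 lower without replicate 1 of the naive group). The responses differed in 4899, 3088 higher and 1811 lower (3157 higher and 2854 lower), and the difference from WT passed in 80, 26 higher and 54 lower (81 higher and 95 lower). The first count was 892 with only the compared groups and 1108 with mitochondrial TPM as a covariate. It was 1895 and 2292 without replicates 1 and 2 of the primed group. The count for the responses was 1633 with the covariate and 2591 to 3210 without replicate 1 or 2 of primed shade, replicate 1 of naive white light or replicate 2 of naive shade. The last ran from 24 to 88 without any 1 of its 16 libraries.

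The size of the response was followed into the mutants over the genes of the WT mean response. That set was chosen in WT and favours it. PIL1 rose in naive and primed seedlings of every line. Genes higher in WT shade had median changes of -0.01 in naive and 0.1 in primed pif7-1, and of 0.28 in naive and 0.22 in primed ref6-1. Genes lower in WT shade had medians of -0.11 and -0.23 in pif7-1 and of -0.29 and 0.06 in ref6-1. For the difference from WT in naive seedlings, camera gave p = 1.29e-45 for the higher and 2.77e-45 for the lower set in pif7-1, or p = 0.00145 and 0.00813 with an estimated correlation, and p = 2.07e-31 and 7.3e-31 in ref6-1, or p = 0.00551 and 0.0238 with an estimated correlation. In primed seedlings p was 2.41e-09 and 6.26e-12 in pif7-1, or p = 0.11 and 0.15 with an estimated correlation, and 2.24e-26 and 4.53e-28 in ref6-1, or p = 0.00961 and 0.03 with an estimated correlation. Between naive and primed responses the total least squares slope was 0.967 (r = 0.33) in pif7-1 and 0.0613 (r = 0.02) in ref6-1. Genes are not independent replicates here. At such r the slope is not the share of a naive change that recurred after priming.

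HSP17.8 and LOX2 stood lower than WT in primed shade in both mutants, HSP17.8 at -2.6 in pif7-1 and -2.57 in ref6-1 and LOX2 at -4 and -2.09. The overlap of their differences from WT was counted in a fit of the 8 WT and 8 primed mutant libraries and set against simulations, because both were compared with the same WT libraries. In primed shade 3840 genes passed for pif7-1 and 1290 for ref6-1. Of these 168 were higher in both (26.1 expected of independent lists), 421 lower in both (96 expected) and 43 opposite. In 40 simulations of unchanged groups against the same WT libraries, the median number called in both with the same sign was 0 and the highest was 1, against 589 observed. The simulations leave out the effects of the mutants and the independent lists leave out the shared controls, so neither is the overlap to expect of lists of this size. The same-sign share of all genes was 66.7%, and 66.5% in the simulations, while r across genes was 0.432 against 0.5. The covariance was 0.102 against 0.033, a difference of 0.0686. For the difference in shade response 275 genes were shared with the same sign (132 higher, 143 lower and 4 opposite, against 11.9 and 26.8 expected of independent lists), with a covariance of 0.244 against 0.0671. WT had 2 libraries per group, too few to split, so part of the excess may come from the shared controls. Without replicate 1 or 2 of shaded WT the overlap in primed shade was 202 and 174, and without replicate 1 or 2 of shaded ref6-1 it was 217 and 228.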

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

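The differences between groups in this paragraph were each found by a test of the difference itself, and the 3 patterns after it by inspecting values per library and lists of called genes. The tests on the ref6-1 libraries and on root markers were chosen after the result was seen, and the test of the genes with opposite signs was written after the principal components had been seen, though not its own value. In WT, the primed and naive shade responses differed in 7594 genes. The shade response of pif7-1 differed from that of WT in 3457 genes after priming and in 2764 in naive seedlings, and that of ref6-1 in 568 and 458. Within pif7-1 the primed and naive responses differed in 489 genes and within ref6-1 in 4899. The change of the response with priming differed from WT in 4076 genes in pif7-1 and in 80 in ref6-1. Averaged over lights, the difference between primed and naive seedlings departed from WT in 1350 genes in pif7-1 (936 higher and 414 lower) and in 2451 in ref6-1 (1123 higher and 1328 lower). These last 2 counts rest on primed against naive mutant levels, which the deposit blocks confound with priming.

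Naive and primed libraries labelled ref6-1 stood apart in 24 genes in which the lowest library of one history was over 2 TPM and over 4 times the highest library of the other, against 4 such genes in WT and 1 in pif7-1. Among them ATXR7 was at or below 0.02 TPM in naive and 7.2 to 8.6 TPM in primed ref6-1, FLC at 2.25 to 5.75 and 79.7 to 84.4 TPM, and AT1G67105 at 3.78 to 5.98 and 384 to 463 TPM. The count of 1 in pif7-1, whose naive libraries share the later block, argues against a technical difference between blocks. Of 35 splits of the 8 libraries 1, the real one, gave as many genes (highest other 16), counted after the separation had been seen. AT1G75945 points the other way, at 27 to 54.2 TPM in naive and 33.6 to 41.4 TPM in primed ref6-1. WT and pif7-1 had at most 1.86 TPM, so both sets share a feature of the line. Priming in ref6-1 plants stays open (2 of the 24 genes set the naive and 11 the primed libraries apart from all WT libraries). Different plant lines with some shared background stay open too, a hypothesis found with the second of 2 criteria. The first (at most 0.5 against at least 5 TPM) gave 2 genes in ref6-1 and 0 in WT and pif7-1. Clock state was not tested. CCA1 stood at 39.8 to 73 TPM in naive ref6-1 (others 96.3 to 223) and GI at 20.6 to 35.4 TPM (others 6.15 to 15.4). TOC1 ranges overlapped.

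In WT 1459 genes passed in opposite directions in the naive and primed shade responses (961 by chance). Of these 1134 fell in naive and rose in primed seedlings, and 325 the reverse. The organelle RNA share, high in naive shaded WT but not in pif7-1, would not carry over to pif7-1. Yet 84.5% of these genes had the WT naive sign in naive pif7-1, which argues against it as the whole cause. That was 95.1% in naive ref6-1, 71.4% in primed pif7-1 and 6.51% in primed ref6-1. A lower root share stays open. Of 13 root markers 10 fell, 4 of which overlap another gene, as does the 1 that rose, ESB1 (0.83). Of the 8 that overlap none 6 fell and 0 rose in limma. A part for organelle RNA (1452 with nuclear genes only) and a response that changes with priming, not tested apart, stay open. Mitochondrial TPM as a covariate (688) cannot decide, being high in naive shaded WT. The count of such genes was 906 without replicate 1 of naive shaded WT, 799 and 968 without replicates 1 and 2 of primed white-light WT, and 789 and 656 without replicates 1 and 2 of primed shaded WT.

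LHCB1.5 and the overlapping AT2G08665 switched between libraries. In 13 libraries LHCB1.5 was at 0 with AT2G08665 at 19582 to 37317 TPM, and in the other 11 at 565 to 23879 TPM with AT2G08665 at 1186 to 21945 TPM. If shared reads went to either member, overlapping pairs would move oppositely more than adjacent pairs. With both genes passing, 44.7% did so in WT naive shade against 37.9% of adjacent pairs, past the 5 points set beforehand. In 2 comparisons added afterwards the shares were 46.2% against 32.9% (WT primed shade) and 45.7% against 46.3% (WT primed minus naive in shade), so crediting of shared reads cannot be told apart from separate regulation. Of the tested genes 34.6% (7424) overlap another gene.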

How the results depend on the processing

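The alternatives, and which were added afterwards, are given above. The organelle covariate is mitochondrial TPM, and 16 libraries is the fit without naive mutants. Counts of called genes stayed within 1.5 times the original under a minimum of 5 TPM, no filter, pseudocounts of 0.1 and 5, nuclear genes only, no overlapping genes and 16 libraries, in each of the comparisons run. Of 1831 pairs of a named gene and a comparison (453 genes), 577 passed under every alternative run. Depth is unknown, so what depth limits could not be computed. In fits without 1 library the lone replicate is assumed to vary like the other groups.

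With only the groups compared, counts were 3450 for WT naive shade, 0 for WT primed minus naive in white light (3567 at an unadjusted p under 0.05 in limma), 4 and 0 for pif7-1 naive and primed shade (4887 and 2521), and 42 and 1109 for ref6-1 naive and primed shade. Against WT they were 1 and 3 for pif7-1 in primed shade and white light (4817 and 5414), and 2013 and 426 for ref6-1. Differences in shade response from WT gave 1465 and 1282 in naive and primed pif7-1 and 66 and 869 in ref6-1. Primed minus naive in shade gave 0 in pif7-1 (3064) and 892 in ref6-1, and the pif7-1 priming by shade interaction 5 (3025). Fewer samples leave fewer residual degrees of freedom in these fits; whether that is the whole cause was not tested.

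With the organelle covariate, counts were 3458 for WT naive shade, 2594 for WT primed minus naive in shade, 2944 for the WT interaction, 1118 for the pif7-1 difference in naive shade response, 1186 for its change with priming, 854 for ref6-1 naive shade, 1108 for ref6-1 primed minus naive in shade and 1633 for the ref6-1 interaction. The total least squares slope of primed against naive WT changes was 0.26, against 0.527 to 0.718 without any 1 library. BBX18 in WT primed minus naive in shade reversed from 0.54 to -0.12. Under quantile normalization, counts were 1863 for pif7-1 minus WT in primed white light, 854 for the pif7-1 interaction and 176 for the ref6-1 change with priming, and LHCB1.3 in the WT interaction went from -0.53 to 0. With an estimated correlation 15 of 624 gene list tests passed, against 220 with the preset one. In these cases the cause was not tested.

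Leave-one-out counts ran from 4763 to 6155 for WT naive shade, 2219 to 3355 for WT primed shade, 6567 to 7323 for WT primed minus naive in shade, 476 to 2240 in white light, 5555 to 6863 for the WT interaction and 3411 to 4346 for the WT mean. In pif7-1 they were 377 to 844 and 178 to 3449 for naive and primed shade, 1386 to 4410 and 154 to 818 against WT in primed shade and white light, 1129 to 2961 and 1409 to 4634 for the difference in naive and primed response, 939 to 4364 for primed minus naive in shade, 47 to 1833 for the interaction and 2521 to 4573 for its difference from WT. In ref6-1, in the same order, they were 1209 to 3465 and 813 to 1535, 522 to 552 and 1236 to 2642, 169 to 944 and 133 to 514, 1895 to 3430, 2591 to 5450 and 24 to 88. The direction with more genes turned in at least 1 fit in 12 of 24 comparisons, in 8 fits for the pif7-1 difference in naive response, 6 for ref6-1 naive shade and 5 for the ref6-1 difference in naive response. The overlap of the mutants, in fits chosen afterwards, ran from 174 to 748. Fewer libraries lower the residual degrees of freedom, and why some omissions raised counts was not tested.

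Replicate numbers did not pair the libraries. Over 66 pairs of groups the median correlation of same-numbered deviations was 0.00172 (-0.117 to 0.132), with 6 over 0.1 and 2 under -0.1. With the number as a replicate block, counts were 7614 for WT naive shade, 5004 for WT primed shade, 955 for pif7-1 primed shade and 93 for the ref6-1 change with priming, and the block moved no count of the 24 comparisons by over 1.5 times.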

Other observations

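The test of splits in this part was written before its result was seen. Seed storage genes, which mark embryos or ungerminated seed, stood high in single libraries. The cruciferin gene CRA1 reached 44.9 TPM in replicate 1 of naive white-light pif7-1, 85.7 TPM in replicate 2 of primed white-light ref6-1 and 48.6 TPM in replicate 1 of primed shaded ref6-1, against 0.49 to 9.74 TPM in the others. Chloroplast transcripts took 7259 to 15264 TPM in naive shaded WT, 4493 to 4554 TPM in naive shaded ref6-1 and 1706 to 9918 TPM in the others. The first principal component held 21 percent of the variance and the second 12.3 percent, and naive shaded WT lay furthest out on the first, at -71 and -65.3.

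Shade against white light in WT, taken as 2 groups of 4 libraries over both histories, gave 2304 genes. Of the 35 splits of these 8 libraries into 4 and 4, 2 gave as many, and the highest other split gave 4158, so this count by itself does not exclude chance. That split set naive white light with primed shade against naive shade with primed white light, the interaction of priming and shade. Splits that match no contrast gave 2145 and 1810.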
